A study of Galleria mellonella with 72 samples.

How the data were processed

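Larvae of Galleria mellonella, the greater wax moth, weighing 300 to 500 mg were infected with strain MM55 of Madurella mycetomatis, a fungus that causes eumycetoma in people, or were kept as healthy controls. Per the labels' protocols, an infected larva was injected in a proleg with 4 mg of mycelium in 40 µL, and treated larvae received itraconazole or ravuconazole at 5.71 mg/kg at 4, 30 and 52 h after infection. RNA was taken at 6, 30, 72 and 168 h, each library being made from the pooled contents of 3 larvae that had been frozen and crushed. The labels name the tissue as hemolymph, so how far other larval tissue entered the pools is open. They do not say whether healthy larvae were injected with anything, whether untreated larvae received the drugs' solvent, or whether the 30 h pools were collected before or after the dose given at 30 h. Every group was taken from the labels for treatment, infection and time, which gives 24 groups of 3 numbered libraries.

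Per the labels' protocols, libraries were made by LQ-ssCAGE, a low-input form of cap analysis of gene expression, in which 200 ng of total RNA is reverse transcribed and the cDNA that reaches a capped 5′ end is captured, with no PCR amplification, and were sequenced as 50-base reads on a HiSeq 2500. Each tag thus marks a transcription start position and its strand. STAR 2.5.3, SAMtools 1.14 and bedtools 2.30.0 are named in the submitters' processing notes, without their roles. The genome build, the treatment of reads that map to several places and any filter on mapping quality are not given in the sources used here. The deposited files hold whole-number counts of tags per genome position and strand, 1 file per library, with no normalization. In each file the positions are on scaffolds of the wax moth genome, and they are given here 1-based. Start sites in near-identical gene copies can have lost or shared tags, depending on how such reads were treated.

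The 72 libraries held 370568 to 801964 tags (median 602299.5) and 42359219 in all, over 1208696 positions on 7384 scaffolds. Of these positions, 60.2% held a single tag in all libraries together. The 30 scaffolds with tags beyond 1 Mb carried 95.5% of the tags. At this depth 1 tag per library is worth about 1 to 3 CPM (tags scaled to the size of the library), so low sites are known only roughly, and ratios against a group with 1 to 3 tags are printed with 95% counting intervals. Where a group held no tag, the fold is a lower bound against a floor of 3 counts over the whole group. Intervals and floors cover counting error only.

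The table of gene names used with this series belongs to another assembly, so no coordinate of it was used and no site was tied to a gene. The feature tested was therefore the tag cluster, the substitute fixed before the data were examined for the case that the builds differ: positions within 20 bp of each other on a strand, pooled over all libraries, with at least 1 CPM pooled. Such a cluster is called a start site here and is named by its scaffold, its strand and the position with most tags. There were 15181 sites, which held 97.8% of the tags, with a median span of 102 bp. The width that holds the middle tags of a site, between its 10th and 90th percentile, had a median of 34 bp. Lists of gene families, counts in windows around annotated starts and the share of sites at annotated starts need gene models and were not analysed here, and the condition that a named gene has an informative product name could not be applied.

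Counts per site were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). Sites were kept by filterByExpr, which left 8006 sites with 97.9% of the tags in sites, libraries were scaled by TMM (factors 0.794 to 1.278), and a quasi-likelihood model with 1 coefficient per group was fitted to all 72 libraries, leaving 48 residual degrees of freedom. The biological coefficient of variation was 29%. Each contrast was tested with glmQLFTest and adjusted by the Benjamini-Hochberg method, and a site was called at an adjusted p under 0.05. Contrasts were infected minus healthy larvae at each time and over the 4 times, the same under each azole, each azole minus no azole and ravuconazole minus itraconazole in healthy and in infected larvae, the interactions of azole and of time with infection, and 168 h minus 6 h in untreated healthy larvae. Contrasts of an azole at single times, and both azole arms' interactions with time, were added later. A change in the use of neighbouring sites was tested with edgeR's diffSpliceDGE and Simes' method over runs of same-strand sites within 1000 bp, a unit that replaced the gene.

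Sites are named by a rule fixed before the data were examined: for infection, the 10 highest and 10 lowest log2 fold changes of each contrast, and for other contrasts 5 and 5, among called sites with at least 5 CPM in the higher group and with groups that did not overlap (over 4 times, with at least 10 of 12 libraries beyond the median of the other group). Fewer are printed than the rule gives. Sites outside it are said to have been chosen after their values were seen. Log2 fold changes come from the model and CPM values are means ± SD of TMM-scaled CPM over libraries. The SE of a log2 fold change is its size divided by the square root of the test's F statistic. It is an approximation and not a standard error given by the model.

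Alternatives fixed beforehand were relative log expression size factors, no filter on low counts, DESeq2 1.42.0 on the same sites, only the libraries compared in each fit, the replicate number as a block, other cluster definitions, a minimum share for start-site use, and leaving out each library in turn. Alternatives added after the data had been examined were tests on the other cluster definitions, the block within fits of only the libraries compared, and means over 6, 72 and 168 h without the itraconazole healthy libraries at 30 h, and also without 1 library at 168 h. Each comparison was also refitted on other splits of its libraries. The most that cross-talk between libraries allows was found by linear programming. The tests were checked on counts simulated from the observed means, dispersions and library sizes with 200 changed sites. For infection at 6 h, 17.2% of sites changed 2-fold and 64.6% of those changed 4-fold were recovered among 7098 sites, with 3 false calls in 80. For infection over the 4 times, 76.1% and 94.6% were recovered among 7129 sites, with 9 false calls in 166. For ravuconazole in infected larvae over the 4 times the shares were 76.9% and 94.7% among 7174 sites, and for the interaction of ravuconazole with infection 44.1% and 86.6% among 7299. For start-site use, 71 of 74 runs with a 4-fold change were recovered among 229, with 1 false call. All pairs of replicates differed by more than counting noise (chi-square per degree of freedom 2.74 to 28.8 over 72 pairs), so each library counted as 1 sample. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.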

Results

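Capped 5′ ends of RNA were counted in larvae of the greater wax moth, an insect host for human fungal pathogens, that were healthy or infected with Madurella mycetomatis and were untreated or given itraconazole or ravuconazole. Both drugs are triazoles, which block ergosterol synthesis in fungi. Itraconazole has a long side chain with a piperazine ring, and ravuconazole is a smaller molecule with a thiazole ring. They were given at the same dose (5.71 mg/kg) and at the same hours. The 72 libraries formed 24 groups of 3, from 3 treatments, 2 infection states and 4 times (6, 30, 72 and 168 h after infection). A library came from a pool of 3 larvae, and p-values measure the spread between these pools, since the labels do not say how separate they were beyond their numbers. Libraries held 565144 ± 103058 tags in healthy and 611501 ± 82082 tags in infected larvae (SD, n = 36 each). Start sites are named by scaffold, strand and main position, as the files give them. They were not tied to genes, because the gene table used here belongs to another assembly. The tags fell into 15181 sites, of which 8006 had enough tags to be tested.

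**Figure D1:**
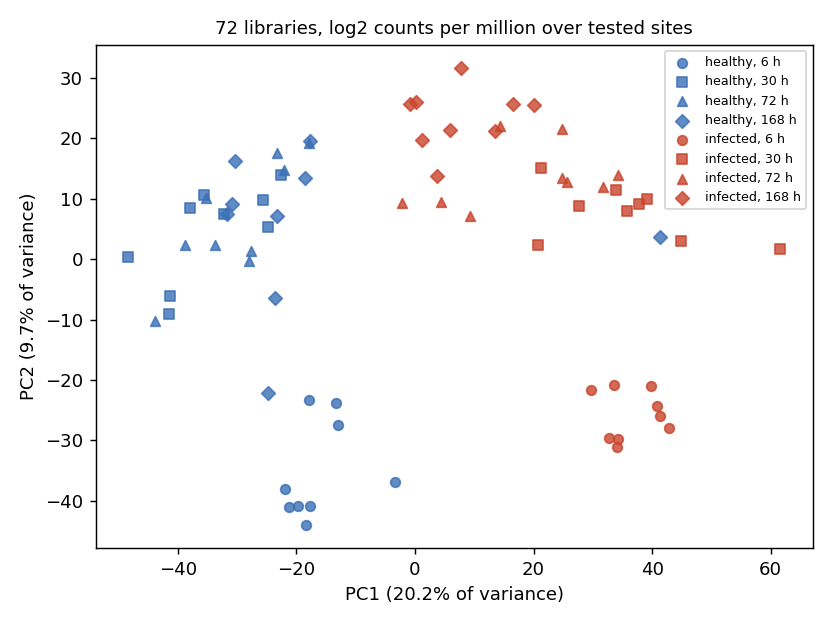
Principal components of log2 CPM over the 8006 tested sites, component 1 (20.2% of the variance) against component 2 (9.69%), with 1 point for each of the 72 libraries, colours for the infection state and shapes for the hours after infection. Infected libraries lie at -2.13 or above on component 1 and 35 healthy libraries at -3.42 or below, while itraconazole healthy replicate 1 at 168 h lies at 41.3.

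Infection in untreated larvae, taken over the 4 times, was marked most by sites in a 41960 bp stretch of scaffold NW_022271163.1 (6750264 to 6792223). The minus-strand site at 6785490 lay at 608 ± 483 CPM in infected and 21.3 ± 43.3 CPM in healthy larvae (SD, n = 12 each), a log2 fold change of 6.54 (SE 0.51, adjusted p = 2.11e-14 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its neighbours at 6790336 (minus), 6792137 (plus), 6774403 (minus), 6750424 (minus) and 6781010 (minus) rose by 6.80, 6.50, 6.37, 5.55 and 5.27 on the log2 scale. Elsewhere, the minus-strand site at 7668248 of NW_022271732.1 rose from 13.8 ± 28.1 to 370 ± 423 CPM and that at 5046440 of NW_022266898.1 from 1.37 ± 1.76 to 28.4 ± 15 CPM. The largest falls among the named sites were at 2701961 (minus) of NW_022272446.1, from 29.9 ± 34.9 to 2.49 ± 3.89 CPM, and at 1569978 (minus) of NW_022269380.1, from 81.4 ± 113 to 3.15 ± 2.89 CPM. The plus-strand site at 378 of NW_022277187.1 fell by 3.63 on the log2 scale (SE 0.49), from 86.5 ± 81.5 to 8.40 ± 9.68 CPM.

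In all, 905 sites were called higher and 954 lower with infection, 404 and 547 of them by more than 2-fold. Some of the sites that changed by more than 2-fold in the same direction lay in runs of at least 4, with gaps of at most 20000 bp. There were 9 runs of raised sites, with 56 of the 404 sites, and 4 runs of lowered sites, with 30 of the 547. When the same numbers of calls were placed at random among the tested sites, the mean was 0.09 runs of raised and 0.19 runs of lowered sites, with at most 2 of either (p = 0.001 for both, the smallest that 1000 permutations can give). This test was chosen after the calls had been seen. It places each site on its own, while sites of a run may be starts of the same gene, which could not be checked without gene models. The test therefore does not show that the sites of a run respond separately.

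The longest lowered run held 15 sites within 19519 bp of NW_022269380.1 (6105458 to 6124976), all 15 also called lower with infection under itraconazole and under ravuconazole. Together these sites fell from 58070 ± 10300 to 12050 ± 688 CPM at 6 h, from 44630 ± 6370 to 8697 ± 5330 CPM at 30 h, from 46180 ± 4260 to 24650 ± 5710 CPM at 72 h and from 37440 ± 6260 to 14150 ± 9880 CPM at 168 h (SD, n = 3 each). On the same scaffold, a run of 4 plus-strand sites (6062594 to 6077206) stood at 24280 ± 3940 CPM in healthy and 1558 ± 259 CPM in infected larvae at 6 h, and at 2821 ± 798 against 130.7 ± 60.8 CPM at 30 h. A run of 7 sites on NW_022271163.1 (14006078 to 14013531) stood at 8816 ± 1230 against 1805 ± 349 CPM at 6 h, and a run of 4 on NW_022268972.1 (8302472 to 8307869) at 170.6 ± 11.7 against 24.06 ± 2.82 CPM. Among raised runs, 10 sites on NW_022270367.1 (4179947 to 4233860) stood at 2610 ± 797 CPM in healthy and 25710 ± 6570 CPM in infected larvae at 30 h, but at 2485 ± 1490 and 1401 ± 641 CPM at 6 h. A run of 7 on NW_022271647.1 (2291819 to 2353130) stood at 947.4 ± 97.2 against 2725 ± 467 CPM at 30 h, and 5 sites on NW_022270926.1 lay within 9092 bp (1408797 to 1417888). The run sums carry no test of their own.

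**Figure D2:**
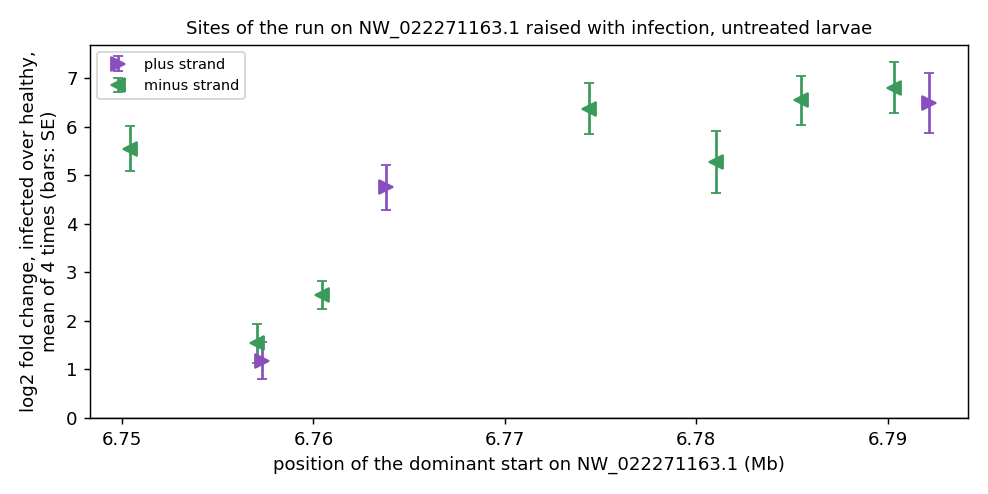
Log2 fold change with infection in untreated larvae (mean of 4 times, error bars 1 SE) of the 10 sites in the raised run of 41960 bp against the position in Mb of the main start on NW_022271163.1, with arrowheads and colours for the strand. 7 sites lie above 4 on the log2 scale, and the other 3 lie under 3.

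At 6 h after infection of untreated larvae, 583 sites were higher and 850 lower. The plus-strand site at 6117646 of NW_022269380.1, within the 15-site run, stood at 2.51 ± 0.43 CPM in infected and 122 ± 61.4 CPM in healthy larvae (log2 fold change -5.52, SE 0.83, adjusted p = 2.24e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). On the same scaffold the minus-strand site at 1569978 stood at 4.75 ± 2.47 against 174 ± 67 CPM, and that at 7395378 of NW_022271459.1 at 2.86 ± 0.37 against 92.0 ± 27.5 CPM. At 12093966 (minus) of NW_022267677.1, 1 tag in infected and 57 tags in healthy larvae gave a ratio of 87.4 (counting interval 15.1 to 3510). Raised sites included 9010032 (minus) of NW_022269380.1, at 14.7 ± 3.91 CPM against no tag, at least 7.82-fold higher, and 9004953 (plus) of NW_022268972.1, at 13.1 ± 4.57 CPM against no tag, at least 6.95-fold higher. The site that the rule ranks first, 791425 (minus) of NW_022271951.1, stood at 85.5 ± 71.1 CPM against no tag (at least 45.4-fold higher). It also held 206 and 166 CPM in untreated healthy replicates 1 and 2 at 168 h.

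At 30 h, 564 sites were higher and 503 lower. The minus-strand site at 7668248 of NW_022271732.1 stood at 909 ± 548 CPM in infected larvae and had no tag in healthy ones, at least 562-fold higher. In the stretch of NW_022271163.1 the minus-strand site at 6790336 stood at 664 ± 77 CPM against no tag, at least 410-fold higher. Its neighbour at 6774403 stood at 2963 ± 338 against 4.35 ± 3.45 CPM (log2 fold change 9.35, SE 1.18, adjusted p = 6.4e-08 by the same test), and that at 6792137 at 3449 ± 2260 CPM against 2 tags, a ratio of 3140 (counting interval 868 to 25900). Lowered sites included 2701961 (minus) of NW_022272446.1, with no tag in infected larvae against 80.6 ± 30.8 CPM, at least 34.5-fold lower, and 2952 (minus) of NW_022276181.1, with no tag against 51.9 ± 18.3 CPM, at least 22.2-fold lower. At 5752717 (minus) of NW_022271647.1 the ratio was 85.2 (23.3 to 708). Without untreated infected replicate 1 the count of calls fell from 1067 to 606.

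At 72 h, 261 sites were higher and 124 lower. The site at 6774403 stood at 2199 ± 1750 against 8.24 ± 1.43 CPM, and 1497755 (minus) of NW_022272446.1 at 355 ± 242 CPM against 3 tags, a ratio of 204 (69.5 to 992). Lowered sites included 2556636 (minus) of NW_022266938.1, at 7.58 ± 0.22 against 123 ± 51.4 CPM. With only the libraries compared in the fit, 244 sites were called in place of 385, 202 with the replicate block, and the count fell to 227 without untreated healthy replicate 2 and to 177 without untreated infected replicate 2. At 168 h, 124 sites were higher and 93 lower. The site at 6774403 stood at 554 ± 230 against 4.98 ± 6.85 CPM (log2 fold change 6.71, SE 1.10, adjusted p = 0.000135 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 14367370 (plus) of NW_022277701.1 at 209 ± 104 against 4.06 ± 5.85 CPM. The minus-strand site at 11518390 of NW_022275502.1 stood at 21.5 ± 26.9 against 388 ± 223 CPM. With only the libraries compared, 99 sites were called in place of 217, 91 with the replicate block, and the count fell to 70 without untreated healthy replicate 1, 118 without healthy replicate 2, 93 without infected replicate 2 and 112 without infected replicate 3.

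**Figure D3:**
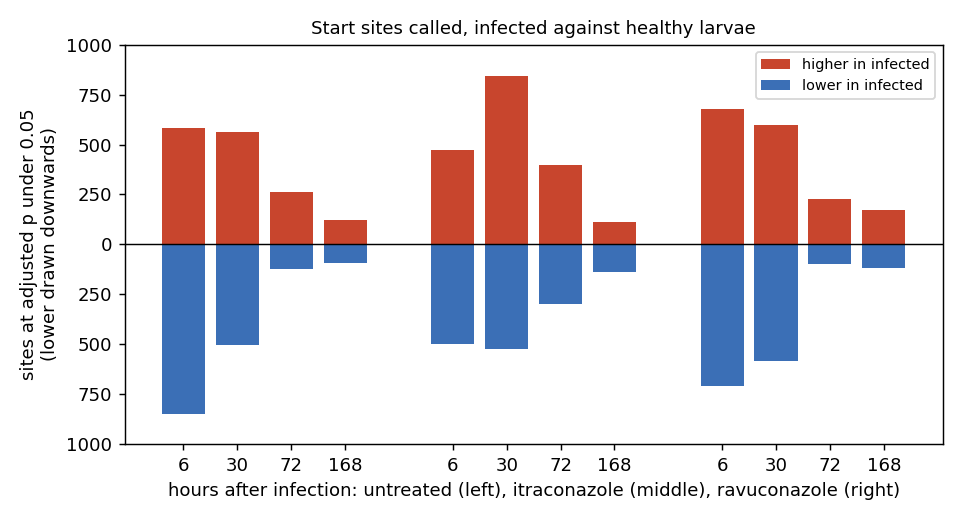
Number of sites called at an adjusted p under 0.05 between infected and healthy larvae, higher in infected larvae drawn upwards and lower drawn downwards, against the hours after infection, for untreated larvae (left), itraconazole (middle) and ravuconazole (right). In untreated larvae the counts go from 583 higher and 850 lower at 6 h to 124 and 93 at 168 h.

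Sites that moved with infection at one time were often called at another, in comparisons that share no library. Of the sites called at 6 and at 30 h, 167 were higher at both, where independent lists would share 41.1, and 263 were lower at both, against 53.4. At 30 and 72 h, 152 were higher at both (18.4) and 60 lower at both (7.8). In all, 21 sites were higher and 11 lower at all 4 times. The infection effect itself differed between 168 h and 6 h at 356 sites in untreated larvae (239 more positive and 117 more negative at 168 h). At 260 of these its estimated sign was opposite at the ends, but only 56 were called at 168 h in the direction of the interaction. At 6 h 275 were called in the opposite direction, and at 268 the effect was smaller in size at 168 h. The largest increase among the named sites was at 14367370 of NW_022277701.1, where the effect was higher at 168 h by 9.04 on the log2 scale (SE 1.27). The largest decrease was at 791425 of NW_022271951.1, the site held by untreated infected larvae at 6 h and by untreated healthy larvae at 168 h. The count was 217 without untreated infected replicate 1 at 6 h, and 236 with only the libraries compared and the replicate number as a block.

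Untreated healthy larvae also changed with time. At 168 h, 5810246 (plus) of NW_022267478.1 stood at 131 ± 79.2 CPM against no tag at 6 h, at least 69.7-fold higher, and 15186520 (plus) of NW_022268972.1 at 57.8 ± 50.8 CPM against no tag, at least 30.7-fold higher. Sites that were raised by infection at 72 h or later were among the falls: 1497755 of NW_022272446.1 stood at 442 ± 442 CPM at 6 h against 3 tags at 168 h, a ratio of 266 (90.7 to 1290), and 6792137 of NW_022271163.1 at 190 ± 316 CPM against 1 tag, a ratio of 323 (57.4 to 12800). The most raised sites of that stretch together held 2017 CPM at 6 h in untreated healthy replicate 2. Replicates 1 and 3 held 207.6 and 189.5 CPM. Whether tags of infected libraries entered there is taken up below. In total 381 sites were higher and 563 lower at 168 h than at 6 h. With only the libraries compared, 581 sites were called, 521 with the replicate block in that fit, and 625 without untreated healthy replicate 1 at 168 h.

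The 7 sites of the raised stretch of NW_022271163.1 that rose by more than 8-fold with infection were summed per library. Untreated infected larvae held 3658 ± 1760, 12400 ± 4100, 5769 ± 4180 and 1390 ± 640 CPM at 6, 30, 72 and 168 h. Untreated healthy larvae held 804.5 ± 1050, 17.9 ± 12, 62.0 ± 30.5 and 23.4 ± 18.2 CPM. Infected larvae given itraconazole held 5974 ± 1360, 2766 ± 305, 2956 ± 1960 and 1580 ± 1560 CPM, and those given ravuconazole 9600 ± 2990, 6095 ± 530, 2763 ± 1060 and 1081 ± 351 CPM (SD, n = 3 each). These sites were picked by their own response, so the sums describe it and carry no test.

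**Figure D4:**
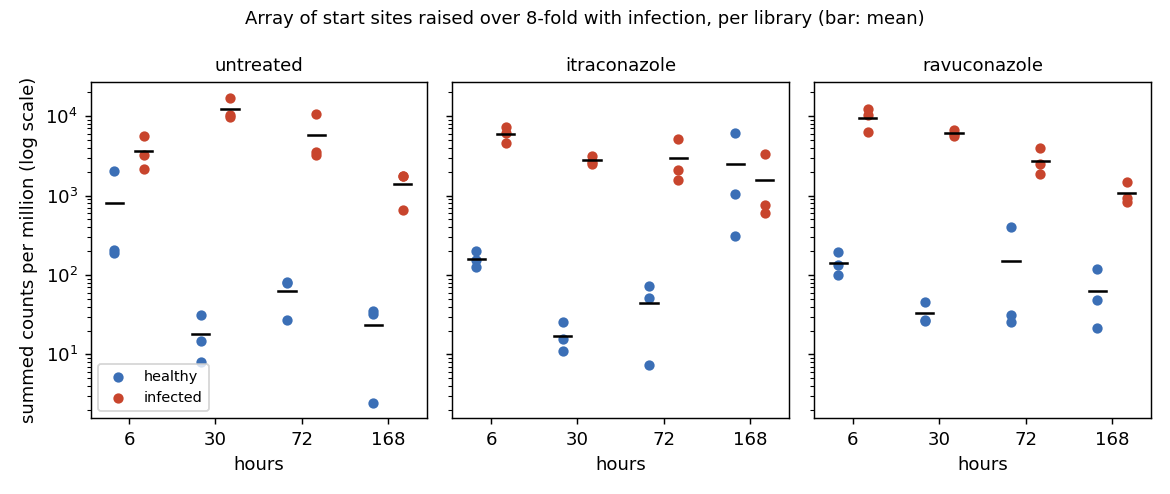
Summed CPM of the 7 sites on NW_022271163.1 (log axis) against the hours after infection, 1 panel per treatment, with a point per library, a bar at each group mean and colours for the infection state. Each infected group mean lies above that of its healthy counterpart except at 168 h under itraconazole, where 1 healthy library reaches 6169.

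Under itraconazole, infected larvae differed from healthy larvae over the 4 times at 1042 sites higher and 780 lower, and under ravuconazole at 1009 higher and 940 lower. Of the 5 highest named sites, 4 under itraconazole and 5 under ravuconazole lay in the raised stretch of NW_022271163.1. There the minus-strand site at 6785490 stood at 400 ± 263 against 39.7 ± 77.6 CPM under itraconazole and at 553 ± 425 against 10.1 ± 14.8 CPM under ravuconazole (log2 fold changes 5.40 and 5.89, SE 0.52 and 0.47, n = 12 each). The plus-strand site at 6062712 of NW_022269380.1 stood at 823 ± 709 CPM in infected and 10300 ± 8470 CPM in healthy larvae under ravuconazole (log2 fold change -4.04, SE 0.49). Under the same drug 2952 (minus) of NW_022276181.1 fell by 5.44 on the log2 scale, to 1.4 ± 2.25 CPM. The 3 arms share no library: 539 sites were higher in the untreated and the itraconazole arm (117.8 for independent lists) and 653 in the untreated and the ravuconazole arm (114.1), while 601 and 668 were lower in both (92.9 and 112). In all 3 arms 482 sites were higher and 517 lower. Under itraconazole the count was 1822 over the 4 times and 1152 over 6, 72 and 168 h with the itraconazole healthy libraries at 30 h left out, a setting that drops both these libraries and the 30 h response.

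In infected larvae, few sites separated azole-treated from untreated animals. Over the 4 times ravuconazole lowered 2 sites: 12556556 (plus) of NW_022276972.1, from 34.1 ± 14.5 to 15.4 ± 7.98 CPM (log2 fold change -1.18, SE 0.21, adjusted p = 0.00534), and 10098468 (minus) of NW_022271163.1, from 23.0 ± 23.2 to 6.85 ± 4.57 CPM (log2 fold change -1.60, SE 0.32, adjusted p = 0.0257 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 12 each). DESeq2 called 8 sites for ravuconazole, and the count was 0 with only the libraries of both groups and the replicate number as a block, 1 without the block and 4 with sites of at least 3 CPM. It was 7 without untreated infected replicate 2 at 30 h, and 4 without untreated infected replicate 1 at 6 h or replicate 3 at 168 h or ravuconazole replicate 3 at 30 h. It was 1 without untreated infected replicate 1 at 30 h, replicates 2 or 3 at 6 h or replicate 2 at 72 or 168 h, ravuconazole replicate 1 at 30 h, or ravuconazole replicate 3 at 6, 72 or 168 h. For itraconazole edgeR called 0 sites at an adjusted p under 0.05, 754 at an unadjusted p under 0.05, and DESeq2 called 17. Leaving out untreated infected replicate 1 at 168 h gave 7 calls and replicate 2 at 30 h gave 6. There was 1 call without untreated infected replicate 1 at 6 h or replicate 3 at 30, 72 or 168 h, or itraconazole replicate 1 at 6 h or replicate 2 at 30 or 72 h. Fits of only the libraries compared called 3 sites, 4 with the replicate block, and sites joined at 50 bp gave 1. The 95% interval of the itraconazole effect lay within 2-fold at 6386 of 8006 sites and that of ravuconazole at 6438.

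At 30 h after infection, itraconazole lowered 55 sites and raised 7 in infected larvae, and ravuconazole lowered 32 and raised 6. At 6, 72 and 168 h itraconazole changed 11, 5 and 0 sites and ravuconazole 9, 4 and 0 (527 and 565 unadjusted at 168 h). The minus-strand site at 7668248 of NW_022271732.1 stood at 909 ± 548 CPM in untreated infected larvae, 75.8 ± 37.1 CPM with itraconazole and 52.8 ± 15.2 CPM with ravuconazole. At 30 h 483871 (plus) of NW_022270124.1 stood at 740 ± 327, 205 ± 24.1 and 154 ± 7.04 CPM (adjusted p = 0.00281 and 0.000393 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 2941020 (minus) of NW_022266129.1 at 494 ± 390, 34.6 ± 22.6 and 28.4 ± 3.29 CPM (n = 3 each). Each of these sites, chosen after its values were seen, was lower in all 6 treated than in all 3 untreated libraries. At 7668248 the untreated replicates 1, 2 and 3 held 1483, 391 and 853 CPM. Of the 55 and 32 lowered sites, 49 and 25 were among those called higher with infection at 30 h in untreated larvae, and 20 were lowered by both drugs. All of these comparisons use the same 3 untreated infected libraries. In 40 simulations of unchanged azole groups against those libraries, a mean of 0.07 and 0 sites were called lower, too few to overlap. Lists of 55 and 32 sites taken by p from each simulation shared a mean of 3.92 sites (at most 7), and a mean of 11.93 and 7.38 of them (at most 20 and 12) were among the simulated calls raised by infection. Independent lists would share 0.22, 3.87 and 2.25. Part or all of the overlap may come from the shared libraries, since 3 cannot be divided. The simulations called almost no sites lower, against the 55 and 32 observed, so their overlaps do not bound that share. Both counts rested on untreated infected replicate 1, which held the highest of the 3 untreated values at 64 of the 67 sites lowered by either drug: without it edgeR called 0 sites for either drug (541 and 451 at an unadjusted p under 0.05). For itraconazole the count of 62 became 115 without untreated replicate 2 and 32, 17 and 17 without itraconazole replicates 1, 2 and 3. For ravuconazole the count of 38 became 66 and 25 without untreated replicates 2 and 3 and 13, 7 and 8 without ravuconazole replicates 1, 2 and 3. Whether the pools at 30 h were taken before or after the dose of that hour is not stated.

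Infected larvae given ravuconazole did not differ from those given itraconazole at any site over the 4 times in edgeR's test, with 378 sites at an unadjusted p under 0.05 and 1 call by DESeq2. Leaving out itraconazole replicate 2 at 72 h gave 1 call. The 95% interval of the difference lay within 2-fold at 6570 of 8006 sites (82.1%), with a median half-width of 0.45 on the log2 scale. At single times 1, 3, 3 and 0 sites were called at 6, 30, 72 and 168 h (423 unadjusted at 168 h), and the interval lay within 2-fold at 33.0% to 34.5% of sites.

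In healthy larvae the 2 azoles differed at more sites at 30 and 168 h (371 and 146, against 3 and 0 in infected larvae). At 6 and 72 h the counts were 2 and 0, against 1 and 3 in infected larvae. Healthy and infected larvae were not tested against each other for this difference. In healthy larvae itraconazole at 30 h lowered 429 sites and raised 43. The plus-strand site at 3728000 of NW_022275502.1 stood at 35.0 ± 35.8 CPM against 1804 ± 660 CPM in untreated healthy larvae (log2 fold change -5.73, SE 0.98, adjusted p = 4.09e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 7217663 (minus) of NW_022270367.1 at 392 ± 295 against 4296 ± 571 CPM, and 11290782 (plus) of NW_022268635.1 at 1052 ± 984 against 4914 ± 1590 CPM (n = 3 each). In infected larvae given itraconazole, these sites stood at 3955 ± 3500, 5190 ± 798 and 7908 ± 2790 CPM at 30 h. They were chosen after their values were seen, from 420 sites that fell by more than 2-fold and together took 0.77% ± 0.33 of the tags in tested sites in the itraconazole healthy libraries at 30 h, against 3.22% to 10.5% in the other 69 libraries. Without itraconazole healthy replicate 1 at 30 h, edgeR called 194 sites in place of 472.

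**Figure D5:**
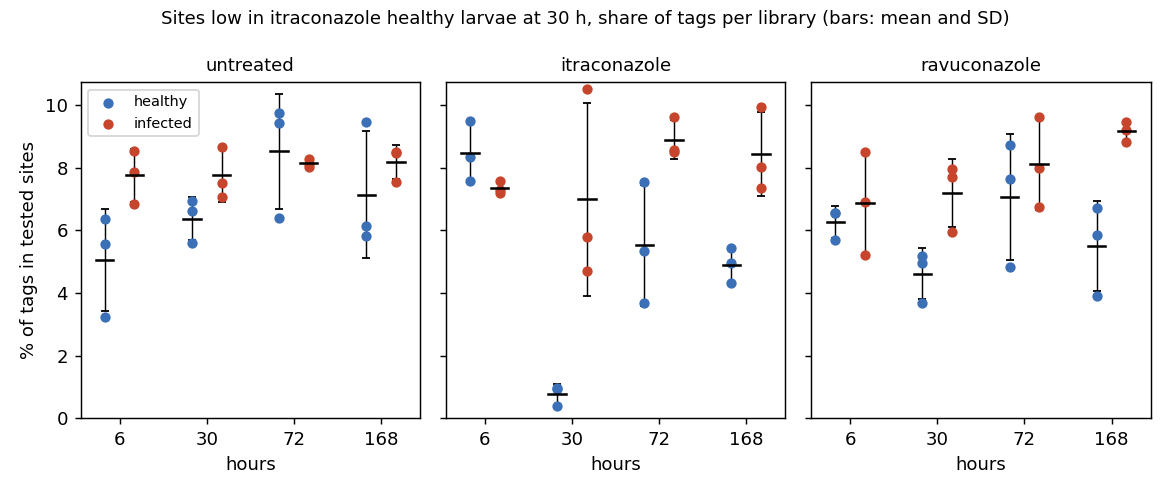
Share of the tags in tested sites, in %, at the 420 sites low in itraconazole healthy larvae at 30 h, against the hours after infection, 1 panel per treatment, with a point per library and bars for mean and SD (n = 3). The 3 itraconazole healthy libraries at 30 h average 0.77% and the other 69 lie between 3.22% and 10.5%.

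At 168 h itraconazole raised 253 sites and lowered 179 in healthy larvae, and 1 of the 3 libraries carried the infection sites of NW_022271163.1 at 6169 CPM. The count of 432 became 222 without that library (replicate 1), 674 without itraconazole replicate 2 and 216 without untreated healthy replicate 1. Of the 253 raised sites, 80 were among the 482 higher with infection in all 3 arms (15.2 for independent lists). Of the 179 lowered sites, 21 were among the 517 lower in all 3 arms (11.6). For ravuconazole at 168 h these overlaps were 2 of 63 (3.8) and 3 of 99 (6.4). The lists share libraries. At 6 h itraconazole raised 7 and lowered 18 sites, and at 72 h it raised 1. Over the 4 times 75 sites were higher and 234 lower, led downward by 7795966 (plus) of NW_022267478.1, from 106 ± 131 to 10.1 ± 20.1 CPM, and upward by 4961698 (minus) of NW_022268635.1, from 1.12 ± 2.24 to 8.48 ± 8.46 CPM. Of the 234 lower sites, 186 belonged to the 420. Over 6, 72 and 168 h only, with the itraconazole healthy libraries at 30 h left out, the count was 34 in place of 309, and 26 when replicate 1 at 168 h was left out too. It was 136 with only the libraries compared, 81 with the replicate block in that fit, and 198 without itraconazole healthy replicate 3 at 30 h.

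Ravuconazole in healthy larvae changed 5 sites over the 4 times. It raised 4653632 (minus) of NW_022272446.1 from 65.9 ± 23 to 209 ± 162 CPM (log2 fold change 1.60, SE 0.29, adjusted p = 0.00774) and 363767 (minus) of the same scaffold from 20.9 ± 17.8 to 159 ± 252 CPM (adjusted p = 0.0489). It lowered 1511708 (minus) of NW_022277701.1 from 138 ± 149 to 45.5 ± 20.5 CPM, 2394008 (minus) of NW_022269869.1 from 161 ± 75.9 to 102 ± 49.4 CPM and 6999367 (plus) of NW_022271163.1 from 210 ± 28.2 to 144 ± 35.3 CPM (adjusted p = 0.0175 each, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 12 each). DESeq2 called 16 sites, and 0 were called with only the libraries compared, with or without the replicate block. The count was 0 without ravuconazole replicate 1 at 168 h (704 unadjusted), 1 without ravuconazole replicate 1 at 72 h or replicate 2 at 30 h, and 9 without ravuconazole replicate 3 at 168 h. It was 2 without untreated healthy replicate 1 at 72 h, replicate 2 at 168 h or replicate 3 at 6 h, and 3 without untreated healthy replicate 1 at 30 h or ravuconazole replicate 3 at 6 h. By time, 4, 5, 0 and 162 sites were called at 6, 30, 72 and 168 h (451 unadjusted at 72 h). The count at 168 h fell to 14 without ravuconazole healthy replicate 2, 48 without untreated healthy replicate 1 and 100 without untreated healthy replicate 2.

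Ravuconazole and itraconazole in healthy larvae differed at 43 sites higher and 13 lower with ravuconazole over the 4 times. The plus-strand site at 4821502 of NW_022266524.1 stood at 45.5 ± 14 CPM with ravuconazole and 22.8 ± 9.51 CPM with itraconazole (log2 fold change 1.00, SE 0.20, adjusted p = 0.00383 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In the other direction, 6371198 (plus) of NW_022272931.1 stood at 25.4 ± 5.87 against 46.4 ± 16.4 CPM. DESeq2 called 122 sites. Over 6, 72 and 168 h only, with the itraconazole healthy libraries at 30 h left out, edgeR called 0, with 777 at an unadjusted p under 0.05. By time 2, 371, 0 and 146 sites differed (832 unadjusted at 72 h). At 30 h 317 were higher with ravuconazole, 255 of them among the 420 sites, and the count was 171 without itraconazole replicate 1. At 168 h it was 21 without itraconazole replicate 1, 325 without itraconazole replicate 2, 253 without itraconazole replicate 3 and 81 without ravuconazole replicate 3. The 95% interval over the 4 times lay within 2-fold at 5995 of 8006 sites (74.9%). The count over the 4 times was 37 without itraconazole replicate 1 at 168 h, replicate 2 at 30 h or replicate 3 at 6 h, or ravuconazole replicate 2 at 72 h. It was 22 without itraconazole replicate 1 at 30 h, 90 without itraconazole replicate 3 at 168 h and 19 without ravuconazole replicate 3 at 168 h. With only the libraries compared and the replicate number as a block it was 13.

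The effect of infection differed between larvae given itraconazole and untreated larvae at 136 sites over the 4 times, 120 more positive and 16 more negative under itraconazole. The named sites included 9116971 (minus) of NW_022277701.1, with an interaction of 4.31 on the log2 scale (SE 0.70, adjusted p = 0.000134), 1955 (minus) of NW_022277573.1, with 4.29 (SE 0.63, adjusted p = 6.31e-05), and 363767 (minus) of NW_022272446.1, with -4.60 (SE 0.93, adjusted p = 0.00204 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of the 120 sites, 101 belonged to the 420 that were low in itraconazole healthy larvae at 30 h. The count was 3 over 6, 72 and 168 h only with those libraries left out, 4 when replicate 1 at 168 h was left out too, and 77 without itraconazole healthy replicate 1 at 30 h. For ravuconazole edgeR found 0 such sites over the 4 times (473 at an unadjusted p under 0.05), and DESeq2 found 2. The count was 1 without untreated infected replicate 1 at 72 h.

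The use of neighbouring start sites changed with infection in 20 of 313 runs of same-strand sites within 1000 bp (edgeR's diffSpliceDGE with Simes' method and Benjamini-Hochberg adjustment). In NW_022269199.1 the plus-strand site at 4529716 gave 25.9% ± 10.1 of its run's tags in untreated healthy and 59.2% ± 19.1 in untreated infected larvae, at the expense of 4529280 (SD, n = 12 each). In NW_022268972.1 the site at 12525739 (plus) went from 41.1% ± 14.6 to 76.0% ± 16.4, over 12526149. In NW_022266524.1 the share of 2261058 (plus) went from 30.6% ± 10.3 to 53.2% ± 10.6, and in NW_022267840.1 that of 1910 (minus) from 37.9% ± 9.52 to 13.4% ± 8.1. In NW_022266898.1 the site at 766437 (minus) went from 1.92% ± 0.92 to 9.65% ± 8.2 (adjusted p = 4.93e-10). These runs were picked after their values were seen. When sites also had to hold at least 10% of a run's tags, 8 runs were called.

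Sites that responded to infection were narrow. Those raised by more than 2-fold spanned a median of 7 bp between the 10th and 90th percentile of their tags, and those lowered 13 bp, against 32 bp in uncalled sites matched on level (28 to 35 and 30 to 35 in 95% of the matched draws, permutation p = 1e-04 for both, the smallest that 10000 draws can give). Pairs of sites on opposite strands that pointed away from each other within 400 bp, the arrangement of divergent promoters and of enhancers, numbered 147. Across these pairs, which are not independent replicates, the infection effects of both members correlated with Pearson's r = 0.594 and Spearman's rho = 0.223 (permutation p = 0.005 for rho, two-sided). In 8 pairs both members were called, in the same direction in all 8, and in 24 pairs 1 member was called. The tests of widths and pairs were chosen after the data had been examined.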

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

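The splits of the libraries were planned before the data were examined. The tests on the low sites at 30 h, on the library at 168 h and on the array at 6 h were chosen after the results had been seen, as were the counts of the interactions at single times and of the interactions with time under each azole.

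The effect of infection differed between 168 h and 6 h at 356 sites in untreated larvae, 582 under itraconazole and 436 under ravuconazole, by edgeR's test of the interaction. Without untreated infected replicate 1 at 6 h the first count was 217, without itraconazole healthy replicate 1 at 168 h the second was 337, and without ravuconazole healthy replicate 2 at 168 h the third was 270. In a fit of the untreated libraries alone the real split called 272 sites, and 7 of 100 splits called as many. The highest, 758, kept every label at 6 h. All 6 other splits that reached 272 were among the 11 that kept or exchanged every label at 6 h, and the 88 that mixed them called 0. The former keep the infection effect at 6 h, so that the share of splits does not measure chance for an interaction and leaves it open.

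The effect of infection differed between itraconazole and no azole at 63, 243, 1 and 104 sites at 6, 30, 72 and 168 h, and at 136 over the 4 times. The count of 63 was 23 without untreated infected replicate 1, 38 without untreated infected replicate 2, 32 without untreated healthy replicate 1, 38 and 29 without itraconazole healthy replicates 1 and 2 and 41 without itraconazole infected replicate 1. The count of 243 was 114 without itraconazole healthy replicate 1 and 125 without itraconazole infected replicate 1. The count of 104 was 14, 250 and 158 without itraconazole healthy replicates 1, 2 and 3, 61 without untreated healthy replicate 1, 63 without untreated infected replicate 3 and 64 without itraconazole infected replicate 3. The count of 136 was 77 without itraconazole healthy replicate 1 at 30 h. Of 100 splits, 1, the real one, called as many sites over the 4 times (106 with only the libraries compared, 55 in the highest other). The splits exchanged azole labels within infection state and time, and random azole labels did not reach that count. They bear on any difference with the azole in either state, so they do not measure chance for the interaction itself. Nor can they tell it from a peculiarity of the itraconazole healthy pools at 30 h.

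For ravuconazole the effect of infection differed from that in untreated larvae at 7 sites at 30 h and 25 at 168 h. The count of 25 was 1 and 52 without ravuconazole healthy replicates 2 and 3, 2, 10 and 15 without ravuconazole infected replicates 1, 2 and 3, 9 and 11 without untreated healthy replicates 1 and 2, and 2 and 16 without untreated infected replicates 2 and 3. Over the 4 times edgeR called 0 sites (473 at an unadjusted p under 0.05, 2 by DESeq2), and all 100 splits called as many, with at most 2.

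The 420 sites low in healthy larvae given itraconazole at 30 h had a median log2 change of -4.09 against untreated healthy larvae, the comparison they were chosen from, whose libraries the interaction of itraconazole with infection at 30 h also uses. Library scaling moves all sites of a library alike, but sites picked without replicate 1, 2 or 3 had a median log2 change in the library left out that differed from that of all other sites by -3.18, -1.70 and -2.07, measured against healthy larvae given ravuconazole (SD of the other sites 0.869, 0.721 and 0.843). An effect of itraconazole on healthy and infected larvae alike is argued against by infected larvae at 30 h, where the same sites had a median log2 change of -0.102 and 3 were called lower. A tissue or cell type largely missing from these 3 pools remains a candidate explanation: within the other groups the sites rose and fell together with a mean correlation of 0.205, where the highest of 200 matched random sets had 0.0056. An effect of the drug limited to healthy larvae stays untested, since these are the only itraconazole healthy pools at that time.

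One of the itraconazole healthy libraries at 168 h, replicate 1, was the only library of 72 whose profile lay closest to a group of the other infection state. A swap with an infected library of this series would put a partner out of place, but 0 infected libraries lay closest to a healthy group. Mixing with RNA of infected larvae at 168 h is argued against by the array on NW_022271163.1, which stood at 6169 CPM in that library and at no more than 3374 CPM in any infected library at 168 h. A wrong label, or RNA of infected larvae of another time, stays open: its correlation across sites with untreated infected larvae at 30 h was 0.451 and with its own group -0.067, which an infection of a healthy pool by another route would also give. Replicates 2 and 3 of the group held the array at 1034 and 307.1 CPM, above all 3 untreated healthy libraries at 168 h (at most 35.5 CPM).

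The array of 7 sites on NW_022271163.1 stood higher in the 9 healthy libraries at 6 h (101.3 to 2017 CPM, median 189.5) than in the 9 at 30 h (7.93 to 45.8 CPM, median 25.3), by 3.36 on the log2 scale (exact permutation within arms, two-sided p = 0.00025, the smallest that 8000 regroupings can give). Index cross-talk from infected libraries cannot be told apart from RNA of the healthy larvae: with all 7999 other sites at or under their upper counting limits, a mixture of the 36 infected libraries could carry up to 632.8 CPM of the array, above the 343.6 CPM held by the 9 libraries together, and the same held without each of them in turn. In untreated healthy replicate 2 alone the limit was 1710 CPM against 2017 CPM held (2218 CPM with limits adjusted for the number of sites). A response to handling or injection may also raise these sites early, which was not tested because the labels do not say what healthy larvae received.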

How the results depend on the processing

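The tests on other cluster definitions, the replicate block within fits of only the libraries compared and the means over 6, 72 and 168 h without itraconazole healthy libraries were chosen after the data had been examined, and the other alternatives before. No result changed direction under any alternative run. With relative log expression size factors and with no filter on low counts, all 18 counts of calls stayed within 1.5 times. With positions of at least 5 pooled tags all counts but that of start-site use, which was not run there, did so. The counts for infection at 6 h and over the 4 times and for infection under ravuconazole stayed within 1.5 times under every alternative. DESeq2 called 16 sites for ravuconazole in healthy larvae, 17 and 8 for itraconazole and ravuconazole in infected larvae, 122 and 1 for ravuconazole against itraconazole in healthy and infected larvae, and 2 for the interaction of ravuconazole with infection. The cause was not tested. With only the libraries compared, which leaves fewer libraries to estimate the spread, the counts were 244 and 99 for infection at 72 and 168 h, 136 and 0 for itraconazole and ravuconazole in healthy larvae, 3 and 1 in infected larvae, and 581 for time. Sites joined at 50 bp gave 1 call for itraconazole in infected larvae, and sites of at least 3 CPM gave 4 for ravuconazole, with the cause not tested. A minimum of 10% of a run's tags left 8 calls of start-site use, with fewer sites tested. Asking for 1 CPM in 3 libraries, met by single tags, gave 79504 sites, against 15181.

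In means over 6, 72 and 168 h only, with the itraconazole healthy libraries at 30 h left out, the counts were 1152 for infection under itraconazole, 34 for itraconazole in healthy larvae, 0 for ravuconazole against itraconazole in healthy larvae and 3 for the interaction of itraconazole with infection. Without replicate 1 at 168 h as well, the last 3 were 26, 0 and 4. Both the times averaged and the libraries changed in this setting, and which of them moved the counts was not tested.

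The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated with a mean r of -0.0018 and of others with 9e-04. With the replicate number as a block the counts were 1408, 1065, 377 and 213 for infection at 6, 30, 72 and 168 h, 1848 over the 4 times, 1812 and 1938 under itraconazole and ravuconazole, 302 and 4 for these drugs in healthy and 0 and 2 in infected larvae, 54 and 0 for the difference between them in healthy and infected larvae, 123 and 0 for their interactions with infection, 348 for infection with time, 930 for time and 21 for start-site use. With the block and only the libraries compared, they were 202 and 91 for infection at 72 and 168 h, 81 and 0 for itraconazole and ravuconazole in healthy larvae, 4 and 0 in infected larvae, 13 for the difference between the drugs in healthy larvae, 236 for infection with time and 521 for time.

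Leaving out each library in turn gave 960 to 1249, 606 to 1003, 177 to 301 and 70 to 228 calls for infection at 6, 30, 72 and 168 h and 1700 to 1917 over the 4 times, 1620 to 2014 under itraconazole and 1832 to 1987 under ravuconazole. It gave 198 to 445 and 0 to 9 calls for itraconazole and ravuconazole in healthy larvae, 0 to 7 and 1 to 7 in infected larvae, 19 to 90 and 0 to 1 for the difference between them in healthy and infected larvae, and 77 to 161 and 0 to 1 for their interactions with infection. It gave 217 to 297 for infection with time, 625 to 766 for time and 18 to 27 for start-site use.

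Of the 177 results for named sites, DESeq2 ended 28 calls and kept 149, no filter ended 11 and kept 166, the block in the fit of all libraries ended 2 and kept 175, and sites joined at 50 bp ended 3 and kept 174. Where a setting could be run for fewer results, the fit of only the libraries compared ended 18 and kept 98, the block in that fit ended 24 and kept 92, sites of at least 3 CPM ended 1 and kept 168, positions of at least 5 tags ended 6 and kept 158, and the means over 6, 72 and 168 h ended 26 and 27 and kept 13 each. Leaving out single libraries ended 339 and kept 2409. Depth limits sites near 5 CPM, where a library holds a few tags. Windows around annotated starts, gene bodies, the share of sites at annotated starts and lists of gene families were planned and not run, because gene models of the files' build were not used.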

Other observations

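The smaller runs of raised sites, the response scores and the profile comparisons were chosen after the data had been examined, and the splits of the libraries before.

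Smaller runs of sites also rose together with infection in untreated larvae over the 4 times. On NW_022269208.1, 8 sites between 5165448 and 5201030 rose by 1.34 to 4.91 on the log2 scale, 3 of them also called under itraconazole and 6 under ravuconazole. On NW_022270926.1, 5 sites between 1408797 and 1417888 rose by 2.54 to 3.46, on NW_022275502.1, 4 sites between 15053381 and 15080444 by 2.07 to 3.51, and on NW_022276972.1, 4 plus-strand sites between 1066108 and 1074898 by 1.34 to 3.36, with all 4 of the last 2 groups called in both other arms. On NW_022269380.1, which also carries 2 lowered runs, 4 sites between 10428067 and 10452141 rose by 1.68 to 2.90. On NW_022270367.1, apart from the longer run on that scaffold, 4 sites between 7212651 and 7231616 rose by 1.39 to 2.24 and were called in both other arms.

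A narrow site was on in a pair of unlike groups. The minus-strand site at 791425 of NW_022271951.1 held 206, 166 and 2.15 CPM in untreated healthy replicates 1, 2 and 3 at 168 h and 37.9, 167 and 51.4 CPM in untreated infected replicates 1, 2 and 3 at 6 h, and no more than 2.47 CPM in any other library. It did not stand alone: sites picked for following it included 801386 (minus) of the same scaffold, 9627140 (minus) of NW_022276972.1 and 4209829 (minus) of NW_022266059.1. Their correlations with it were 0.961, 0.839 and 0.742.

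Of the 72 libraries, 50 lay closest to their own group among the 24, and 71 to a group of their own infection state.

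Whether an azole weakened the response to infection was tested on sites that changed by more than 2-fold in the arm of the other azole, as the mean of each site's standardized log2 CPM. In infected larvae given itraconazole, 473 raised sites scored 0.144 lower than in untreated infected larvae (0.503 ± 0.23 against 0.647 ± 0.268, SD, n = 12 each, lower at 4 of 4 times, exact permutation within times, two-sided p = 0.111, adjusted 0.214 over 12 tests), and 521 lowered sites scored 0.183 higher (higher at 4 of 4 times, p = 0.0734, adjusted p = 0.176 by the same exact test). In those given ravuconazole, 602 raised sites scored 0.121 lower (3 of 4 times, p = 0.0288, adjusted p = 0.115 by the same exact test) and 409 lowered sites 0.142 higher (4 of 4 times, p = 0.125, adjusted p = 0.214 by the same exact test). No score passed the correction (smallest adjusted p 0.176 for itraconazole and 0.115 for ravuconazole). In healthy larvae the same 602 sites also scored lower with ravuconazole than without an azole, by 0.234 (p = 0.0225, adjusted p = 0.115 by the same exact test), and the 409 lowered sites scored 0.14 higher (p = 0.0196, adjusted p = 0.115 by the same exact test). The response itself, infected minus healthy, was therefore compared between arms over 6 tests, with arm labels permuted within infection state and time. For ravuconazole it was 0.862 against 0.75 at the raised and -1.143 against -1.145 at the lowered sites (permutation adjusted p = 0.524 and 0.983, two-sided), and for itraconazole 1.044 against 1.11 and -0.877 against -1.125 (adjusted p = 0.835 and 0.44 by the same permutation test, n = 24 in each arm). The itraconazole healthy libraries include replicate 1 at 168 h, whose profile lay closest to an infected group, which makes the itraconazole difference smaller. The 3 at 30 h would make it larger: at the 482 sites higher with infection in all 3 arms they scored -1.27, -0.981 and -1.041. Untreated healthy libraries at 30 h scored -0.692, -0.66 and -0.624 there. Scores of the 12 itraconazole healthy libraries had SDs of 0.507 and 0.477 at the raised and lowered sites. In untreated healthy larvae the SDs were 0.161 and 0.158. The comparison was not repeated without these libraries. A smaller response stays open for both drugs. For ravuconazole neither the raised nor the lowered sites pointed to one, but they were picked in the itraconazole arm. The healthy side of that arm includes the pools at 30 h that were low at 420 sites, and the overlap with these was not counted.

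Other splits of the libraries bear on each count of calls, in fits of only the libraries compared. For infection at 6, 30, 72 and 168 h the real splits called 1284, 983, 244 and 99 sites and the highest of the other 9 called 0 each time, and for time in untreated healthy larvae 581 and 0. With 10 splits, of which 1 reached the real count, these are too few for a share under 0.05. For infection over the 4 times the real split called 1719 sites and was the 1 of 100 to reach that count, with 797 in the highest other, in which all labels at 6 and 30 h were exchanged. Under itraconazole it was 1 of 100 (1453 against 113) and under ravuconazole 1 of 100 (1809 against 141). It was 1 of 100 too for itraconazole in healthy larvae (136 against 91) and for start-site use (16 against 5). No other split thus reached any of these 5 counts, a share under 0.05. It is the smallest share that 100 splits can give and was not adjusted for the number of counts tested. For itraconazole in healthy larvae the highest other split kept all 6 labels at 30 h and exchanged all at 168 h. The splits cannot tell that count from a peculiarity of the itraconazole healthy pools at 30 h. For itraconazole in infected larvae 3 of 100 splits, the real one among them, reached the real 3 calls, with at most 7. This share is under 0.05 but was not adjusted for the number of counts tested. Another split called more sites than the real one, and the fit of all libraries called 0 (754 unadjusted, DESeq2 17). Chance therefore stays open for this count.

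Chance also stays open for the remaining counts over the 4 times. For ravuconazole in infected larvae 5 of 100 splits reached the real 1 call, with at most 6. For ravuconazole against itraconazole in healthy larvae 7 of 100 reached the real 38, with at most 95. All 6 others that reached it were among the 15 splits that kept or exchanged every label at 30 h, and the 84 that mixed them called 0, so the splits that reached it also keep the differences of that time. For ravuconazole in healthy larvae, for ravuconazole against itraconazole in infected larvae and for the interaction of ravuconazole with infection, the fits of the libraries compared called 0 sites in edgeR (561, 404 and 487 at an unadjusted p under 0.05, and 16, 1 and 2 by DESeq2 on all libraries), so that all 100 splits reached it, with at most 1, 4 and 2.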
